A study of Homo sapiens with 18 samples.

How the data were processed

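The series measured RNA of PANC-1 cells with a control shRNA (shSCR) or a shRNA against RBM42 (shRBM42), 3 gradients each, in 3 pools of polysome fractions. Per the labels' protocols, 1 or 2 µl of a 1 in 200 dilution of ERCC spike-in RNA was added to each pool according to its RNA amount, and libraries were made from 10 ng of RNA with a stranded kit for total RNA of low input. Which pool received which volume is not stated there. Reads were assigned with Salmon on hg38, per the submitters' processing notes, which give no version. The deposited table holds 12171 genes, 12170 of them protein-coding in GENCODE, so a selection of genes had been made that no note describes. Mitochondrially encoded and noncoding genes were not analysed here.

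The 6 untranslated columns hold whole read counts as deposited. The 12 columns of the low and high pools hold a spike-in scaled signal, per the file headers, in which the deposited value of each gene is a whole read count times a single factor per library. Whole reads were recovered from the step between values for 100% of values in every library, within a tolerance of 0.001 read. Because the untranslated library of each gradient has a factor of 1, each gradient is scaled to its own untranslated library, and the deposited scale is not comparable between gradients. Within a gradient it is comparable only if the factors allow for the volume of each pool, which no note states. The columns name their pools by terms of gradient practice and not by fraction, and their match to the 3 pools was inferred. The design had foreseen scaled values in all columns; since the untranslated columns turned out to be counts, edgeR replaced limma as the main test there, and limma became an alternative. Fits of recovered reads in the low and high pools, and of their ratio, were added after the data were examined; they give changes relative to the other genes of a pool. The other designs, the gene lists and the rule for named genes were fixed before the data were examined, and some alternatives were added after it. Totals ranged from 8387916 to 19446116 reads per library.

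The low and high pools and the shSCR baseline, the per-gradient ratio of high to untranslated signal and the sum over pools were fitted with limma 3.58.1 (R 4.3.3) on log2 of the value plus a pseudocount of 1, with a mean-variance trend. Pools were fitted on all 18 libraries with 1 mean per group (12 residual degrees of freedom), and ratios were centred on the median gene of each gradient. A filter of at least 10 in at least 3 libraries removed no gene. Counts and recovered reads were fitted with edgeR 4.0.16 (quasi-likelihood, TMM scaling), and as an alternative with DESeq2 1.42.0. The ratio of reads was fitted in edgeR on 18 libraries with the gradient as a block. Adjusted p values are Benjamini-Hochberg, with a threshold of 0.05, and rest on 3 gradients per shRNA. The limma fits of pools count the 3 pools of a gradient as independent and share their spread across genes. Their p values therefore do not measure the spread between gradients alone. Counts between replicates of a group varied beyond counting error (chi-square per degree of freedom of at least 6.36), so depth was not the main limit of precision. Shares and CPM were compared with two-sided exact permutation tests.

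Replicate numbers pair the gradients: after removal of group means, same-numbered shSCR and shRBM42 libraries of a pool correlated at 0.109 to 0.553 across genes, differently numbered ones at −0.507 to 0.133, and 17 of 18 libraries correlated best with their own number. The labels do not say what the numbers share. The main fits had no block, and fits with the replicate number as a block were alternatives.

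Named genes were RBM42 and MYC in every comparison, and the 10 largest rises and falls of the high pool and of the ratio (5 in other comparisons). They had to pass the threshold, show no overlap between the 3 values of each shRNA and reach a mean deposited value (not reads) of 100 in a group. Where fewer passed, those with the lowest p were named as not passing. A random gene has a 10% chance of no overlap between 3 and 3. The rule left out 62 clone-style or pseudogene symbols. Gene lists were tested with camera (preset correlation 0.01 and estimated correlation) and fry. They were small-subunit (RPS) and large-subunit (RPL) ribosomal proteins, other TOP mRNAs, initiation factors, aminoacyl-tRNA synthetases, growth and oncogenic drivers, MYC targets, ATF4 and integrated stress response genes, ER chaperones, cytosolic chaperones, mitosis, DNA replication, replication-dependent histones, p53 targets, OXPHOS, splicing factors, cholesterol synthesis, glycolysis and hypoxia, mesenchymal, epithelial, interferon, NF-kB, proteasome and zinc finger genes, and markers of other cell types. Lists of mitochondrially encoded mRNAs, long noncoding RNAs and small nuclear and nucleolar RNAs had 0 measured members. Positions and UTRs came from GENCODE release 29 on hg38.

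Fits were tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold. edgeR recovered 82% and 99% of these in the high pool, 85% and 99% in the low pool, 76% and 97% in the untranslated pool, and 54% and 90% in the ratio. limma recovered 0% and 48% in the high pool and 3% and 49% in the low pool with the deposited factors, 46% and 91% in the ratio, 48% and 100% in the sum and 80% and 98% in the shSCR baseline. A planted list was called and 0 of 25 random lists were. The simulated genes varied independently, so this does not test lists whose members vary together. Simulated libraries also varied independently, with no effect shared by a replicate number, so the recovery rates need not hold for the real data. Alternatives covered pseudocounts, filters, scaling, trend, library weights, blocks, other tools, other ratios, exchanged spike-in factors and each left-out gradient.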

Results

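Polysome sequencing was made of PANC-1, an established cell line of pancreatic ductal adenocarcinoma, to ask what the RNA-binding protein RBM42 does in translation. Cells carried a control shRNA (shSCR) or a shRNA against RBM42 (shRBM42). Each lysate was parted on a gradient, and fractions 3 to 6, 7 to 10 and 11 to 14 were pooled as the untranslated, low-translation and high-translation pools. With 3 gradients per shRNA and 3 pools per gradient, 18 libraries in 6 groups of 3 were measured over 12171 genes. The libraries held 8387916 to 10248439 gene reads in the untranslated pool, 11638476 to 19107271 in the low pool and 13726428 to 19446116 in the high pool.

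RBM42 mRNA was depleted from the low and high pools of shRBM42 cells, with no detectable change in the untranslated pool. In the high pool RBM42 averaged 323 ± 16.1 CPM (edgeR's depth-scaled read count; SD, n = 3) in shSCR and 41.1 ± 14.1 CPM in shRBM42 cells, 12.7% of control. In the low pool it averaged 129 ± 24.2 CPM in shSCR and 19.7 ± 1.89 CPM in shRBM42 cells, 15.3% of control. In the untranslated pool the levels were 70.3 ± 6.07 and 71.7 ± 10.1 CPM. The gene (ENSG00000126254; 10 exons on hg38 chromosome 19, 35629030 to 35637686) gave 4163 to 5296 reads per shSCR and 493 to 1007 per shRBM42 library of the high pool. By edgeR's quasi-likelihood test it fell 7.85-fold in the high pool (log2 change −2.97, SE 0.22, adjusted p = 0.00123) and 6.53-fold in the low pool (−2.71, SE 0.16, adjusted p = 3.84e-05). The edgeR change in the untranslated pool was 0.03 (SE 0.15, 95% interval −0.30 to 0.35, adjusted p = 0.958). Two-sided exact permutation tests of the CPM gave p = 0.1 in the low and high pools, the smallest value that 3 against 3 allows, and p = 0.8 in the untranslated pool. On the deposited spike-in scale, limma gave −2.40 (SE 0.50, adjusted p = 0.00570) in the high pool and −1.99 (SE 0.50, adjusted p = 0.0571) in the low pool. That fit counts the 3 pools of a gradient as independent, so its p values do not measure the spread between gradients alone. Its scale is not comparable between gradients, so these changes hold on that scale only. The limma call in the high pool was lost without shSCR replicate 2 (−2.42, adjusted p = 0.179) and without shRBM42 replicate 1 (−2.14, adjusted p = 0.465), 2 (−2.70, adjusted p = 0.118) or 3 (−2.35, adjusted p = 0.475). It was also lost with the 6 libraries of the pool alone (−2.40, limma adjusted p = 0.803), array weights (−2.26, 1.00), spike-in offsets in edgeR (−2.61, 1.00) and spike-in size factors in DESeq2 (−2.61, 0.547). In the low pool RBM42 passed with pseudocount 10 (−1.96, limma adjusted p = 0.0488), without trend (−1.99, 0.0355), in the 6 libraries alone (−1.99, 0.0112), centred (−2.67, 9.54e-08), with TMM scaling (−2.69, 2.58e-05) and with array weights (−1.52, 2.84e-13). It passed there as well with edgeR spike-in offsets (−2.05, adjusted p = 0.0246), exchanged factors of shSCR replicate 3 (−1.52, 1.14e-05), and without shSCR replicate 1 (−2.06, 0.00110) or 3 (−1.69, 3.47e-05).

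**Figure D1:**
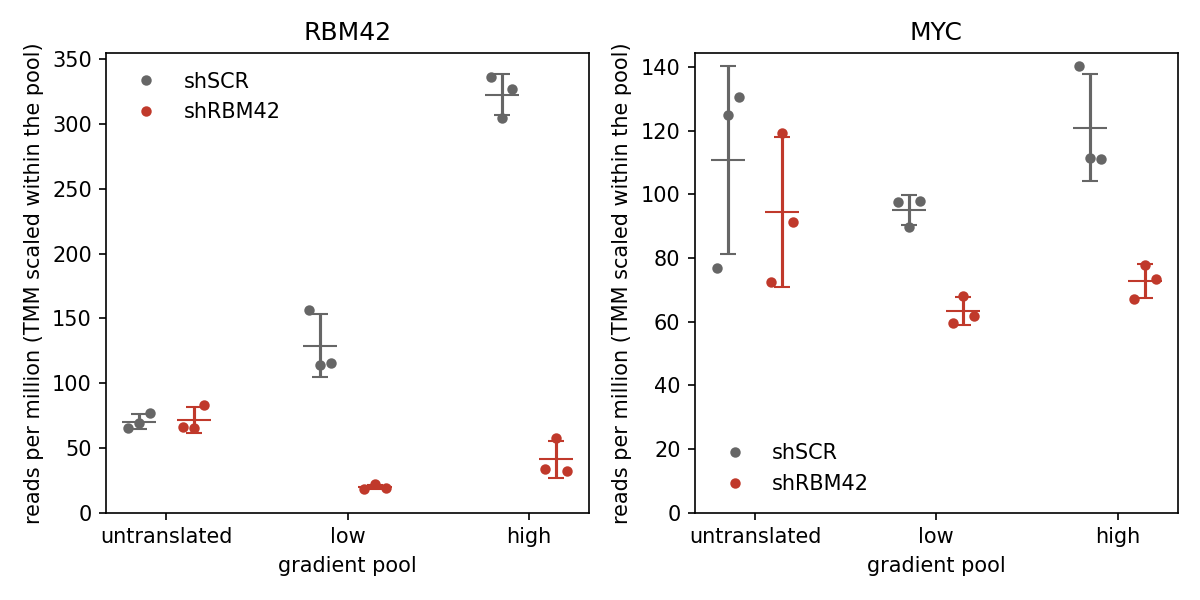
CPM of RBM42 and MYC (TMM-scaled within each pool) by pool and shRNA; points are libraries, lines the mean and SD of 3. RBM42 averaged 41.1 CPM in the high pool of shRBM42 cells against 323 in shSCR, and 71.7 against 70.3 in the untranslated pool; MYC averaged 72.7 against 121 in the high pool.

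The share of mRNA signal in each pool was asked about next. The high pool held 48.8 ± 3.13% (SD, n = 3) of the summed deposited signal of shRBM42 gradients and 48.1 ± 24.7% of shSCR gradients. The low pool held 33.7 ± 1.11% and 32.0 ± 20.6%, and the untranslated pool 17.5 ± 2.17% and 19.9 ± 5.21%. The shSCR gradients were far apart, with 71.6%, 50.4% and 22.4% of signal in the high pool for replicates 1, 2 and 3, against 45.2%, 50.4% and 50.8% for shRBM42. The spike-in factors of shSCR replicate 3 were 1.43 in the low and 0.543 in the high pool, against 0.755 and 2.60 in replicate 1 and 0.568 and 1.43 in replicate 2, and 1.13 to 1.31 and 1.65 to 1.76 in shRBM42. Two-sided exact permutation tests gave p = 0.8 for the high, 1 for the low and 0.4 for the untranslated share, so that no difference was detectable beyond this spread with the factors as deposited. With the low and high factors of shSCR replicate 3 exchanged, the low share of shSCR was 20.5 ± 6.05%; the exchange was chosen after the values were seen and itself brings these gradients together, so that no test of the shRNA rests on it. The labels give the spike-in volume as 1 or 2 µl without naming the pools, so that the shares hold only if the deposited factors allow for it. The median gene's log2 ratio of high to untranslated signal was 1.45 ± 0.31 in shRBM42 and 1.05 ± 1.08 in shSCR (n = 3 each, exact permutation p = 0.6).

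**Figure D2:**
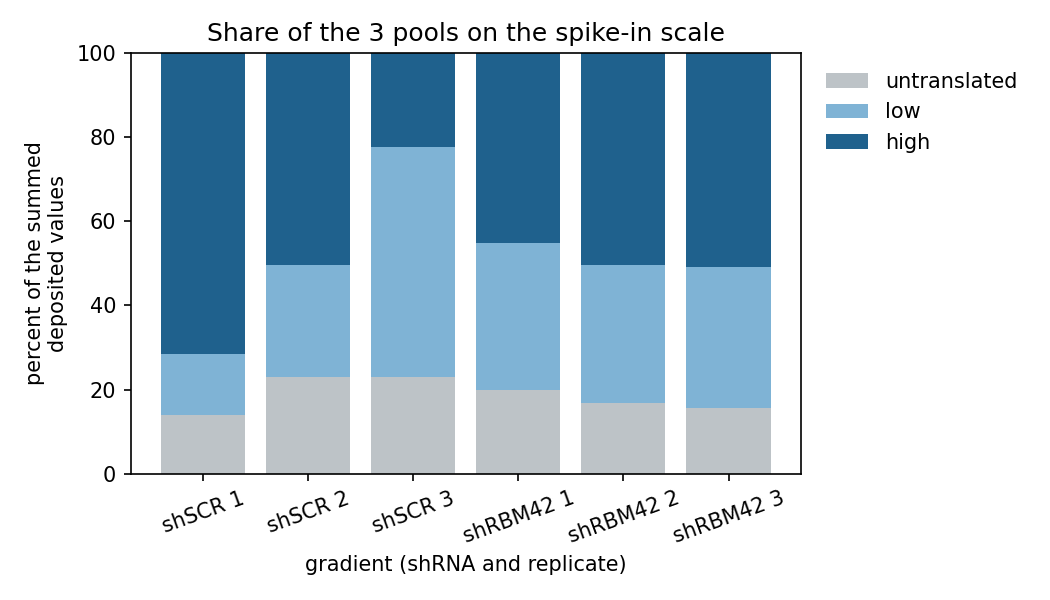
Percent of the summed deposited signal in the untranslated, low and high pools of each of the 6 gradients, as stacked bars. The high pool spans 22.4% to 71.6% in the shSCR and 45.2% to 50.8% in the shRBM42 gradients.

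In the high pool of shRBM42 cells, AHNAK2, AHNAK and MYC were among the mRNAs that fell relative to the other genes. Of the named genes, the giant scaffold proteins AHNAK2 (5.02-fold) and AHNAK (4.79-fold) fell most after RBM42 itself. Also lower were GIPC3 (4.64-fold), the imprinted gene MEST (4.64-fold), the cytokine receptor kinase JAK1 (4.55-fold), FBXL16 (4.24-fold), TMEM64 (3.92-fold), the Ran importer NUTF2 (3.67-fold) and the poly(rC)-binding protein PCBP4 (3.60-fold). The transcription factor MYC fell 1.66-fold (log2 −0.73, SE 0.14, edgeR adjusted p = 0.0188), from 121 ± 16.8 to 72.7 ± 5.41 CPM (n = 3). The stress-induced mTORC1 inhibitor SESN3 had the largest rise among the named genes, 3.81-fold (log2 1.93, SE 0.25, edgeR adjusted p = 0.00599). Other rises were LAT2 (3.33-fold), MPZL3 (3.00-fold), the synaptic vesicle protein SYT1 (2.84-fold), the dynein light chain DYNLRB1 (2.79-fold), KLHDC3 (2.74-fold), the mitochondrial dehydrogenase HSD17B10 (2.70-fold), the mRNA-binding protein CPEB3 (2.54-fold), ARHGEF37 (2.53-fold) and EVI5L (2.43-fold). The edgeR test of recovered reads called 882 genes, 316 risen (35.8%) and 566 fallen (64.2%), and with library totals in place of TMM 472 risen (52.0%) and 435 fallen (48.0%). The count was 2842 with the replicate number as a block, which held all 882, and 1540 with DESeq2. It was 1616 without shSCR replicate 1, 114 without shSCR replicate 3, 103 without shRBM42 replicate 1 and 28 without shRBM42 replicate 3, and the MYC call was lost without each of the latter 3 (edgeR adjusted p = 0.0664, 0.101 and 0.120). Of the 10 named falls, 9 held the sequence GCCCAA, chosen after the data were seen, in their coding sequence or 3' UTR. MYC held it too, as did 4 of the 10 named rises and 50.4% of all genes.

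**Figure D3:**
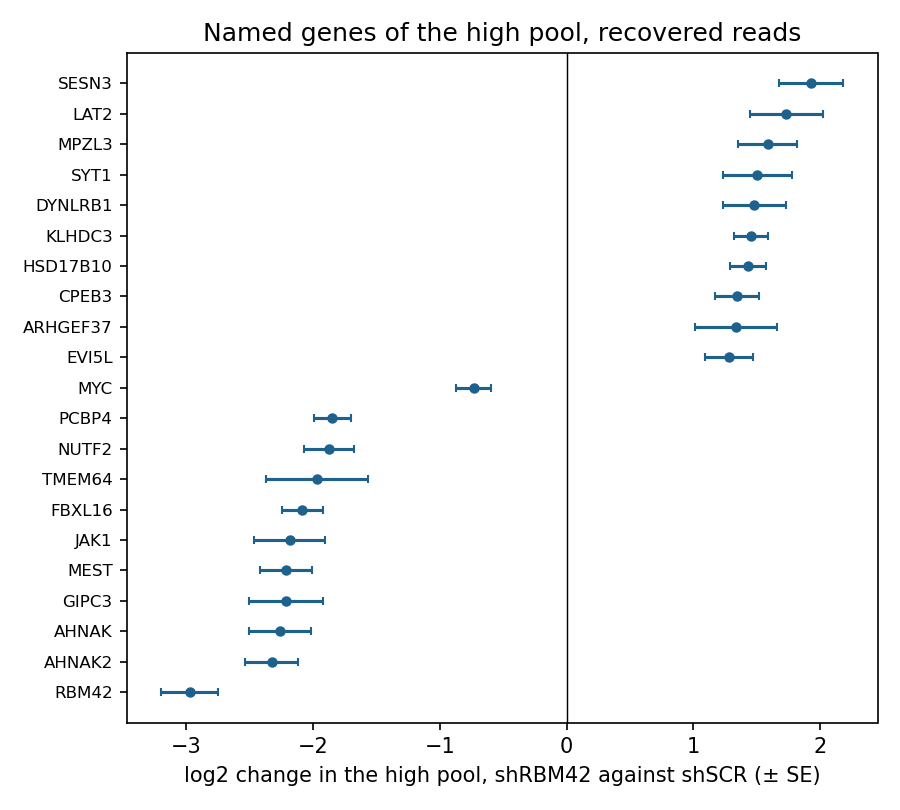
Log2 change (shRBM42 against shSCR, edgeR on recovered reads) with its SE for the 21 named genes of the high pool, n = 3 per shRNA. RBM42 lies lowest at −2.97 and SESN3 highest at 1.93; MYC lies at −0.73.

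On the deposited spike-in scale, where the median gene lay 0.62 higher (log2) in the high pool of shRBM42 cells, few genes stood out. That median was 1.18 without shSCR replicate 1, 0.05 without shSCR replicate 3, 0.16 with the 2 factors of replicate 3 exchanged and 0.36 with edgeR or DESeq2 on the spike-in scale, so that its size rests on single gradients. The scale is not comparable between gradients, so the changes in this paragraph hold on it only. It rests on the untranslated libraries, which were all deeper in shRBM42 cells, and the median gene there lay 0.23 higher. SESN3 (5.63-fold), DYNLRB1 (4.52-fold), KLHDC3 (4.23-fold) and HSD17B10 (4.20-fold) rose and RBM42 fell. MPZL3, LAT2, CPEB3, ZNF709, EVI5L and USP53 did not pass on the rising side (limma adjusted p = 0.0685 to 0.158), nor did MEST on the other (log2 −1.61, limma adjusted p = 0.232), and MYC was at −0.10 (SE 0.50, limma adjusted p = 0.881). Centred on the median gene MYC passed at −0.71 (limma adjusted p = 0.0200), and with TMM scaling at −0.73 (0.0172). In all, limma called 9 genes, 6 risen (66.7%) and 3 fallen (33.3%). With each library centred on its median gene 698 rose and 695 fell, and with TMM scaling 318 rose and 574 fell. The other calls were EGFL8 and RBAK-RBAKDN, risen, and SERF1A and SMIM11B, fallen, named after their values were seen; the last 3 share reads with near-identical or readthrough copies and are uncertain. The count was 9494 without shSCR replicate 1, 3 without replicate 2 and 81 without replicate 3, and 1, 1 and 3 without shRBM42 replicates 1, 2 and 3. With the 2 spike-in factors of shSCR replicate 3 exchanged it was 166.

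By gene list, the replication-dependent histones stood apart, nearly as much in the low and untranslated pools as in the high pool. Of 41 measured, 27 fell over all genes and 37 when adjusted over the list alone, among them HIST1H1E (log2 −1.48), HIST1H1B (−0.96), HIST1H2AG (−0.83) and HIST1H2AH (−0.78), although near-identical copies share reads. Their median change was −0.66 (camera adjusted p = 6.41e-22; adjusted p = 0.936 with an estimated correlation), and −0.02 on the deposited scale against 0.62 for the median gene, which shifted with shSCR replicates 1 and 3 as given above. Without shSCR replicates 2 and 3, 13 and 2 histones fell, and without shRBM42 replicates 1 and 3, 1 and 0. Of 15 histones with GCCCAA 12 fell in the high pool, and of 26 without it 15 fell. With the replicate block the histone median was −0.65 in the high, −0.52 in the low and −0.48 in the untranslated pool. In the blocked ratio of high to untranslated reads it was −0.16. MYC target genes had a median of −0.36 relative to the other genes and 0.29 on the deposited scale (camera adjusted p = 0.00115; adjusted p = 0.936 with an estimated correlation). Of 48, 3 fell by both adjustments: the ribosome biogenesis factor TCOF1 (−1.42), the chaperonin HSPD1 (−1.30) and the spermidine synthase SRM (−0.81). Of the MYC targets 19 fell and 2 rose with the replicate block, 5 and 9 fell without shSCR replicates 1 and 2, 1 without shSCR replicate 3, and 0 without shRBM42 replicate 1 or 3. Zinc finger transcription factors had a median of 0.20, and 0.83 on the deposited scale (camera adjusted p = 0.00391; adjusted p = 0.936 with an estimated correlation). Of 63, 6 rose and 1 fell (7 and 1 adjusted over the list alone), with ZNF91 at 1.05, ZNF680 at 0.93, ZNF805 at 0.66 and ZNF367 at 0.54. With the replicate block 12 rose and 4 fell. Without shSCR replicate 1, 10 rose, and 0 without shSCR replicate 3 or shRBM42 replicate 1 or 3.

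Of 47 proteins of the large ribosomal subunit 4 fell in the high pool, RPL7A (−1.46), RPL29 (−0.84), RPL32 (−0.82) and RPL5 (−0.61), with a list median of −0.13, and 0.50 on the deposited scale (camera adjusted p = 0.0333; adjusted p = 0.936 with an estimated correlation). Without shSCR replicate 3 or shRBM42 replicate 1 a single one fell, and without shRBM42 replicate 3 none. The edgeR test called 0 of 32 small-subunit proteins, 0 of 19 other mRNAs with a 5' terminal oligopyrimidine (TOP) tract and 0 of 20 aminoacyl-tRNA synthetases (camera adjusted p = 0.230, 0.176 and 0.218). Of 38 initiation factors, MCTS1 rose (0.62) and EIF6 fell (−0.86). With the replicate block, edgeR called 6 large-subunit and 2 small-subunit proteins, 3 other TOP mRNAs and 2 synthetases, all fallen, and 4 risen and 5 fallen initiation factors.

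Of 56 growth and oncogenic drivers, 2 rose and 5 fell (3 and 9 adjusted over the list alone), the falls including the AP-1 subunit FOSL1 (−1.41), the cyclin CCND3 (2.00-fold), MYC and the kinase AKT2 (−0.66). Of 22 p53 targets, 2 rose and 3 fell (7 and 5 adjusted over the list alone), among them the ribonucleotide reductase subunit RRM2B (0.62), the stress cytokine GDF15 (−1.37), TNFRSF10B (−0.61) and AEN (−0.48). Of 10 NF-kB and secreted inflammatory genes ICAM1 (−0.81) and RELB (−0.58) fell, and the list's camera adjusted p of 0.0676 was 0.0189 with the replicate block, as was that of the 24 cytosolic chaperones (0.0704 without it), of which HSPA4L fell (−0.74). In the blocked fit both lists had an adjusted p = 0.887 with an estimated correlation. In the other lists at most 1 member passed without the block. TOP2A (−1.43) of 39 mitosis genes, POLD3 (−0.76) of 38 DNA replication genes, IFRD1 (−0.56) of 23 ATF4 and integrated stress response genes, and CREB3L2 (−0.58) of 23 ER chaperone and unfolded protein response genes fell. CYC1 (−0.70) of 46 nuclear-encoded OXPHOS genes, SRRM2 (−0.78) of 50 hnRNP and SR splicing factors, ESRP2 (−0.68) of 18 epithelial genes and IRF7 (−0.62) of 26 interferon response genes also fell. STARD4 (1.04) of 24 cholesterol synthesis genes and PFKFB4 (0.90) of 26 glycolysis and hypoxia genes rose. edgeR called 0 of 33 mesenchymal and extracellular matrix genes and 0 of 31 proteasome subunits. With the replicate block, edgeR called 8 risen and 10 fallen growth drivers, 7 and 5 p53 targets, 1 and 7 mitosis genes, 2 and 3 ER chaperone genes, 4 and 2 OXPHOS genes, 6 and 1 cholesterol genes, 6 and 4 mesenchymal genes, 3 and 1 epithelial genes and 1 and 2 interferon genes. There 11 DNA replication genes, 7 cytosolic chaperones, 6 splicing factors, 5 NF-kB genes, 5 ATF4 genes and 3 proteasome subunits fell with 0 risen, and 3 glycolysis genes rose with 0 fallen.

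The low pool changed along with the high pool. MEST and AHNAK2 (each 4.24-fold), FBXL16 (3.69-fold) and NUTF2 (3.41-fold) fell with RBM42 relative to the other genes, while CCDC181 (4.92-fold), DYNLRB1 (3.01-fold), CHIC1 (2.83-fold), MYH15 (2.80-fold) and the glucocorticoid-induced leucine zipper TSC22D3 (2.69-fold) rose. MYC fell as well (log2 −0.59, SE 0.12, edgeR adjusted p = 0.0173), from 95.1 ± 4.64 to 63.2 ± 4.37 CPM (n = 3), a call lost without shSCR replicate 3 (adjusted p = 0.0938) and shRBM42 replicates 1 (0.0697) and 3 (0.105). The low and high pools shared 140 rises (9.81 for independent lists) and 322 falls (23.6 for independent lists), both being pools of the same gradients. edgeR called 886 genes in the reads of the low pool, 378 risen (42.7%) and 508 fallen (57.3%), and 482 risen (52.9%) and 429 fallen (47.1%) with library totals. The count was 3662 with the replicate number as a block and 1399 with DESeq2. It was 423 and 240 without shSCR replicates 2 and 3, and 322 and 78 without shRBM42 replicates 1 and 3.

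On the deposited scale, where the median gene of the low pool lay 0.71 higher in shRBM42 cells (0.48 and 1.08 without shSCR replicates 1 and 3, and 1.17 with the factors of replicate 3 exchanged), limma called 10 genes. CCDC181 (7.48-fold), DYNLRB1 (5.10-fold) and CHIC1 (4.73-fold) were among 9 rises (90.0%), and the only fall was SMIM11B. These changes too hold only on that scale, which is not comparable between gradients. SFXN3 and KLHDC3 (limma adjusted p = 0.0559), AHNAK2, MEST, FBXL16 and MDK (0.293 to 0.294) and MYC (log2 0.11, SE 0.50, limma adjusted p = 0.846) did not pass, and MYC was at −0.59 with TMM scaling (limma adjusted p = 0.0173), 0.51 with array weights (2.41e-05) and 0.58 with the factors of shSCR replicate 3 exchanged (0.0513). Centred on the median gene, 375 rose and 382 fell, and with TMM scaling 385 and 520. The count was 23, 2 and 9878 without shSCR replicates 1, 2 and 3, and 5, 5 and 3 without shRBM42 replicates 1, 2 and 3. With the 2 factors of shSCR replicate 3 exchanged it was 11150.

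The ratio of high to untranslated signal within each gradient asks which mRNAs changed differently in these 2 pools. RBM42 was lower in it 8.26-fold (log2 −3.05, SE 0.27, limma adjusted p = 0.00255), a limma call lost without the mean-variance trend (adjusted p = 0.187), uncentred (−2.64, adjusted p = 1.00) and in the ratio of high signal to the sum of pools (−0.63, adjusted p = 1.00). By edgeR's test with the gradient as a block, the deubiquitinase USP2 (3.18-fold), the nucleolar factor AATF (3.06-fold), the linker histone HIST1H1E (3.04-fold), JAK1 (2.97-fold), the Polycomb protein CBX6 (2.71-fold), RAB11FIP1 (2.66-fold), the helicase DDX41 (2.61-fold), PMP22 (2.58-fold) and CYBC1 (2.54-fold) also fell. ZC3HAV1L (2.76-fold), the interferon-induced membrane protein BST2 (2.58-fold), the ubiquitin-conjugating enzyme UBE2W (2.07-fold), MINDY2 and PCMTD1 (each 2.00-fold), RMND5A (1.92-fold), the sterol carrier STARD4 (1.91-fold), FAM126B and LIMS1 (each 1.89-fold) and HECTD2 (1.87-fold) rose. MYC was at −0.51 (SE 0.24, edgeR adjusted p = 0.316, and SE 0.29, limma adjusted p = 0.625). With a gradient left out edgeR placed MYC between −0.67 (without shSCR replicate 3) and −0.17 (without shSCR replicate 1). edgeR called 91 genes, 20 risen (22.0%) and 71 fallen (78.0%), against 39 with library totals, 12 risen and 27 fallen. Of the 10 named falls 9 held GCCCAA in the coding sequence or 3' UTR, as did 6 of the 10 named rises. A separate fit of the 6041 genes without GCCCAA alone, with its own scaling and adjustment, called 1. In the fit of all genes, 7 fallen and 10 risen genes had no GCCCAA in either region, among 5765 such genes with both regions annotated. In the 3' UTR 65.2% of the fallen genes held it, against 21.9% of the uncalled and 30.0% of the risen genes. edgeR called 437 with the replicate number as a further block, 8 with the gradients unpaired, 287 and 36 without shSCR replicates 2 and 3, and 3, 19 and 2 without shRBM42 replicates 1, 2 and 3. By limma, RBM42 was the only gene past the threshold (1077 at an unadjusted p under 0.05), or 62 genes with the replicate block, 4 without shSCR replicate 1 and 2 without shRBM42 replicate 2. Among genes that did not pass, the lowest limma p on the lower side were those of AATF, RPL7A, CBX6, JAK1, HIST1H1E, CYBC1, SF3A1, CNNM2 and DDX41 (limma adjusted p = 0.129 to 0.227). On the higher side they were UBE2W, NPIPA5 (uncertain, as near-identical copies share reads), LIMS1, FAM126B, PCMTD1, ZC3HAV1L, CCL28, HIPK3, BST2 and RMND5A (limma adjusted p = 0.321 to 0.345).

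By list, 9 of 25 lists lay lower in this ratio by limma's camera, each by a small amount. All 47 large-subunit ribosomal proteins were lower (median log2 −0.29, adjusted p = 1.75e-07 by limma's camera), with 30 of 32 small-subunit proteins (−0.26, 8.70e-05), 18 of 19 other TOP mRNAs (−0.29, 0.000867) and 18 of 20 aminoacyl-tRNA synthetases (−0.32, 0.00195). Each of these 4 had an adjusted p = 0.736 with an estimated correlation. Cytosolic chaperones (−0.31, adjusted p = 0.000221 by limma's camera), MYC target genes (−0.28, 0.000506), mitosis genes (−0.25, 0.00333), ER chaperones (−0.17, 0.0179) and splicing factors (−0.20, 0.0187) were lower as well. Each of these 5 likewise had an adjusted p = 0.736 with an estimated correlation, and none of the 9 was called by fry (lowest adjusted p = 0.120). The initiation factors were not called (25 of 38 lower, median −0.07, limma camera adjusted p = 0.492). limma called 0 of their members over all genes. Adjusted over the list alone, 2 cytosolic chaperones, 1 large-subunit protein and 1 MYC target fell. In edgeR's ratio of reads with the replicate block, 5 MYC targets, 4 mitosis genes, 4 splicing factors, 3 cytosolic chaperones, and 1 each of the large-subunit proteins, synthetases and ER chaperones fell over all genes. Adjusted over the list alone, 15 MYC targets, 11 synthetases, 11 cytosolic chaperones, 11 mitosis genes, 10 splicing factors, 8 other TOP mRNAs, 2 large-subunit proteins and 1 ER chaperone fell there. Camera called 11 lists in that fit, the same 9 with histones (median −0.16, adjusted p = 0.00220) and DNA replication genes (−0.07, 0.0181). These had an adjusted p = 0.819 and 0.759 with an estimated correlation, and 3 members of each fell over all genes. The ratios were centred on the median gene; uncentred, every gene lay 0.41 higher, so that all 9 medians turn positive, but with the factors of shSCR replicate 3 exchanged that shift was −0.06.

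The untranslated pool asks whether mRNA accumulated off the ribosome. The genes with the lowest p among those with separated replicates were lower PXMP2 (log2 −1.72), FBXL16 (−1.17), SEC16A (−0.91), JMJD4 (−0.87) and the rRNA methyltransferase DIMT1 (−0.82), and higher MTBP (1.02), NUP188 (0.78), UBASH3B (0.62), ZNF708 (0.58) and VRK1 (0.52), each at an edgeR adjusted p of 0.443. MYC was at −0.23 (SE 0.22, edgeR adjusted p = 0.727), and between −0.44 (without shSCR replicate 1) and −0.07 (without shRBM42 replicate 1) with a gradient left out. edgeR called 0 genes in this pool, with 1223 at an unadjusted p under 0.05, and 0 with the replicate block. DESeq2 called 27, all fallen, of which 23 also fell in the high pool (1.26 for independent lists), and 0 with the block. limma on the 18 libraries called 3, NPIPA3, NPIPA5 and TRIM6-TRIM34, which share reads with near-identical or readthrough copies and were named after their values were seen. That fit did not scale the counts for depth. Its median gene lay 0.23 higher in shRBM42 cells, whose untranslated libraries were all deeper. Without shSCR replicate 2, edgeR called 101 genes, 28 risen and 73 fallen.

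Sums over the 3 pools of a gradient rest on the deposited scale, which is not comparable between gradients and where the median gene lay 0.45 higher in shRBM42 cells, so that the following changes hold on that scale only. TRO (4.84-fold), the lipopolysaccharide co-receptor CD14 (4.54-fold), vitronectin (VTN, 4.03-fold), CCDC181 (3.89-fold) and DYNLRB1 (3.82-fold) rose. RBM42 (3.85-fold), AHNAK2 (3.47-fold), CORO7-PAM16 (2.99-fold, a readthrough gene and uncertain), MEST (2.96-fold) and AHNAK (2.78-fold) fell, and MYC was at −0.20 (SE 0.28, limma adjusted p = 0.590). limma called 446 genes, 429 risen (96.2%) and 17 fallen (3.81%), but 10 risen and 53 fallen when each gradient was centred on its median gene, and 217 risen and 404 fallen when centred with the replicate block. MYC fell in the last fit (log2 −0.64, limma adjusted p = 0.0386), but its centred change did not pass without the block (limma adjusted p = 0.0869). The count was 9384, 159 and 157 without shSCR replicates 1, 2 and 3, 0, 93 and 0 without shRBM42 replicates 1, 2 and 3, and 1978 with the factors of shSCR replicate 3 exchanged.

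In shSCR cells alone, mRNAs were spread widely between the high and untranslated pools. The collagen COL5A2 (log2 3.58), SOGA1 (10.3-fold) and the receptor NOTCH2 (8.60-fold) lay on the high side relative to the median gene, as did the readthrough genes NDUFC2-KCTD14 (9.91-fold) and CORO7-PAM16 (9.75-fold), which are uncertain. The ferritin light chain FTL (38.5-fold), a classic mRNA under translational repression, SELENOW (27.1-fold), MARCH2 (24.2-fold), TCTE3 (23.4-fold) and the poly(A)-binding protein PABPC1 (22.7-fold), itself a TOP mRNA, lay on the untranslated side. RBM42 lay 4.83-fold toward the high pool (log2 2.27, limma adjusted p = 2.01e-06), and MYC was at 0.23 (limma adjusted p = 0.336). limma called 8056 genes, 4062 toward the high and 3994 toward the untranslated pool.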

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

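Of the tests in this part, the test of sampling noise and the edgeR test of the ratio were chosen after the result was seen. Groups of 3 were not tested for outlying libraries.

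The effect of the shRNA on RBM42 differed between pools: its log2 change in the high pool lay 3.05 below that in the untranslated pool (limma on the ratio, −3.05, adjusted p = 0.00255), where its reads did not fall. Sampling noise in the untranslated libraries is argued against by the lower 95% bound of the change there, −0.30, far above the high pool's −2.97. Reads of an overlapping annotated gene are argued against by 0 annotated genes with an exon overlapping an RBM42 exon on the same strand. Reads of a gene of like sequence elsewhere were not tested. A general damping of changes in the untranslated pool is argued against by its slope of 0.49 on the high pool changes over genes called in the low pool. This slope predicts −1.45 for RBM42 (−1.16 by the slope within fallen genes with GCCCAA and −0.80 within risen genes). RBM42 RNA in the untranslated fractions that escapes the shRNA, such as unspliced or nuclear RNA, or fragments of cleaved RBM42 mRNA, may account for this and was not tested. Biological and technical sources of this kind cannot be parted by gene totals.

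edgeR on reads, with the gradient as a block, found 91 genes whose shRBM42 effect differed between the high and untranslated pools. Of these, 17 rose and 57 fell in the high pool as well (0.519 and 3.30 for independent lists), but the ratio is made from the same high pool libraries. Of the 91, 7 fallen and 10 risen genes had no GCCCAA in the coding sequence or 3' UTR, among 5765 such genes with both regions annotated. A separate fit of the genes without GCCCAA alone, with its own scaling and adjustment, called 1.

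The 6 gradients allow 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 886 genes in the reads of the low pool (highest other 1), 882 in the high pool (1), 91 (0) in the edgeR and 1 (0) in the limma ratio, 446 (83) in the sum, 10 (3) in the low pool on the deposited scale and 0 (1) in the untranslated pool, so that there all 10 splits were as large. In the high pool on the deposited scale it gave 9 genes, and 3 of the 10 splits gave as many. A split that joined shSCR replicate 1 with shRBM42 replicates 2 and 3 gave 8331, which points to a structure of the samples other than the shRNA; as the reads of the high pool gave 0 in that split, it goes with the deposited spike-in scale. That split parts all 3 numbered pairs, as 4 splits do with the real one; the highest of the other 3 was 0 for the low reads, both ratio results, the sum and the untranslated pool, and 1 for the high reads and the low pool on the deposited scale. For the shSCR baseline, exchanging the pools of 1 gradient gave 4 arrangements, with 8056 genes in the real one and 0 as the highest other. Reversing 1 of 3 gradients that lie the same way must lower the count, and 4 arrangements are too few for a share under 0.05. This comparison therefore decides nothing about the baseline.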

How the results depend on the processing

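Exchanged spike-in factors, fits of reads, DESeq2 in the untranslated pool, the centred sum with a block, library totals in place of TMM, genes without GCCCAA, unpaired gradients in edgeR, spike-in offsets in the low pool, and the alternatives for RBM42 other than centring were chosen after the data were seen. The count of the shSCR baseline (6997 to 9860) stayed within 1.5 times under all alternatives run. The high pool's share of signal (difference −12.2 to 12.4) and the median gene shift from untranslated to high (−0.14 to 0.94) changed sign between alternatives, within a spread that shSCR replicate 3 widened, so that their direction is open. The low pool's share differed by 1.72 as deposited and by 13.2 with exchanged factors. Leaving out mitochondrial and ribosomal RNA genes was not run, as the table has 0 of them, and leaving out genes by the filter of 10 in 3 moved nothing. Among named genes, 154 of 1350 gene and setting pairs lost and 133 gained the threshold in the high reads, 137 and 49 of 1108 in the ratio of reads, and 45 and 182 of 2140 in the high pool as deposited. The only reversal was MYC in the low pool, at −0.59 with TMM scaling (limma adjusted p = 0.0173). Where the cause of a change is not given by the alternative itself, the cause was not tested.

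RBM42 in the high pool, −2.40 by limma, stayed lower in every alternative (−3.02 to −1.81) and lost its call with edgeR spike-in offsets (−2.61), DESeq2 spike-in size factors (−2.61), array weights (−2.26) and the 6 libraries alone (−2.40, adjusted p = 0.803). With a gradient left out it ranged from −2.96 to −1.81, with adjusted p from 3.43e-14 to 0.475.

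In the untranslated pool (0 genes by edgeR), DESeq2 called 27, limma 3, limma with pseudocount 0.5 5, without filter 3, without trend 6, centred 4 and with array weights 3228; leaving out a gradient gave 0 to 101. In the low pool (10), the filter of 100 gave 3, spike-in offsets 22, exchanged factors 11150, no trend 50, array weights 11693, centring 757, the 6 libraries alone 91, TMM 905 and left-out gradients 2 to 9878. In the high pool (9), the filter of 100 gave 4, spike-in offsets 1 in edgeR and 0 in DESeq2 (230 at an unadjusted p under 0.05), exchanged factors 166, no trend 39, array weights 0, centring 1393, the 6 libraries alone 1, TMM 892 and left-out gradients 1 to 9494.

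In the limma ratio (1), no trend gave 0 (982 at an unadjusted p under 0.05), array weights 659, the replicate block 62, no centring 4, unpaired libraries 9, high over the sum 0 (406 at an unadjusted p under 0.05), low over untranslated 6 and left-out gradients 1 to 4. In the sum (446), array weights gave 10720, centring 63 and 621 with the replicate block, exchanged factors 1978 and left-out gradients 0 to 9384. In the low reads (886), the replicate block gave 3662, DESeq2 1399 and 2587 with the block, genes without GCCCAA 257 and left-out gradients 78 to 1236. In the high reads (882) the same gave 2842, 1540, 2187 and 230, and 28 to 1616. In the ratio of reads (91), unpaired gradients gave 8, low over untranslated 5, genes without GCCCAA 1, library totals 39, the replicate block 437 and left-out gradients 2 to 287. Fewer genes were tested without GCCCAA.

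Of the gene lists called by camera in the ratio (9) and the high pool (3), an estimated correlation and fry called 0, as they did on the edgeR fits except 1 list of the ratio by fry (NF-kB genes, adjusted p = 0.0428). Left-out gradients gave 6 to 10 lists in the ratio and 3 to 9 in the high pool. The array weights converged poorly on the deposited scale. Of the simulated 2-fold changes, limma found 0% in the high pool with the deposited factors, and edgeR 82% in its reads. The simulated libraries varied independently, with no effect shared by a replicate number, so these rates are not the limit of detection of the real data.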

Other observations

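The tests of the base order of the 3' UTR and of the spike-in factors were chosen after the results were seen. In shSCR cells, all 31 proteasome subunits lay toward the high pool (median log2 1.40, limma camera adjusted p = 1.96e-10), as did 30 of 33 mesenchymal and extracellular matrix genes (1.51, 1.23e-07), 20 of 24 cytosolic chaperones (1.11) and 18 of 23 ER chaperones (1.26). Toward the untranslated pool lay 44 of 63 zinc finger transcription factors (−0.77, limma camera adjusted p = 2.19e-06). The ribosomal proteins were divided, with 26 of 47 of the large and 20 of 32 of the small subunit on that side. With an estimated correlation none of the lists was called (lowest adjusted p = 0.212), and by fry 21 were. These counts are relative to the median gene.

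In the untranslated pool, camera placed 40 of 41 histones lower in shRBM42 cells (median −0.50, edgeR camera adjusted p = 2.77e-15) and mitosis genes (0.22, 0.000688), zinc finger genes (0.12, 0.00822), ER chaperones (0.18, 0.00822) and ribosomal proteins of both subunits (0.15, 0.00825 for the small and 0.16, 0.00827 for the large) higher. No call remained with an estimated correlation (adjusted p = 0.822 for each of these), and edgeR without a block called 0 members, over all genes or adjusted over the list alone. With the replicate block 31 histones, 2 NF-kB genes and 1 initiation factor fell and 4 mitosis and 4 ER chaperone genes rose when adjusted over the list alone, and 0 over all genes. The other TOP mRNAs joined these lists with the block (camera adjusted p = 0.0279; adjusted p = 0.741 with an estimated correlation). In the low pool, 19 of 41 histones fell and 1 rose (median −0.53), 7 of 48 MYC targets fell (−0.28), 7 of 63 zinc finger genes rose (0.22), and 4 of 31 proteasome subunits (−0.21), 0 of 24 cytosolic chaperones (−0.28) and 2 of 10 NF-kB genes (−0.33) fell, relative to the other genes. Their edgeR camera adjusted p were 2.86e-18, 0.000133, 2.88e-05, 5.90e-05, 0.00702 and 0.0131, and 0.719 or above with an estimated correlation. Of these, fry called the zinc finger genes alone (adjusted p = 0.0378 on the edgeR fit), and none with the replicate block (0.0906). With the block 39, 25, 14, 13 and 6 members of the other lists fell in the same order, 25 zinc finger genes, 2 MYC targets and 1 histone rose, and 2 zinc finger genes fell. On the deposited scale the first 4 medians were positive, 0.18, 0.44, 0.91 and 0.48 in the same order, against 0.71 for the median gene. Without shSCR replicates 1, 2 and 3, 36, 6 and 2 histones fell, and without shRBM42 replicates 1 and 3, 3 and 2. Without shSCR replicate 3 and shRBM42 replicates 1 and 3, 2, 3 and 0 MYC targets fell, 1 zinc finger gene rose each time and 1 proteasome subunit fell each time; without shSCR replicate 2 these last counts were 2 and 2. Of 27 markers of other cell types 5 were measured: CD68 at 126 CPM, SYT1 at 2.81, LYZ at 1.75, HBA1 at 1.44 and PDGFRB at 1.34; of these SYT1 alone rose in the high pool.

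Genes with GCCCAA in the 3' UTR had lower changes in the high pool of shRBM42 cells, the lowest of 4096 hexamers (z = −18.2, with −16.9 in the low and −8.21 in the untranslated pool). GCCCAA was chosen after these data were seen. Its rank and the shares of genes with it therefore describe the data and are no independent test. Of the genes that fell in the high pool 49.1% held it, against 18.7% of those that rose and 20.99% of the uncalled genes. Fisher's exact test of the fallen against the uncalled genes gave an odds ratio of 3.62 (p = 3.33e-44, across genes that are not independent). The next order of the same bases in the high pool was AGCCCA, at z = −8.82 (−7.79 in the low pool). As GCCCAA was picked as the lowest hexamer, no other order could lie lower, so the comparison does not decide on composition of the 3' UTR. The z of AGCCCA is close to 0.5 times that of GCCCAA, a limit set after the values were seen, and AGCCCA shares the run GCCCA with it. In the untranslated pool −4.81 is over 0.5 times the z of GCCCAA, which leaves composition open there as well. Composition of the coding sequence is argued against by z = −13.9 among genes without the hexamer in the coding sequence, with coding GC and length as covariates. Among genes without a 3' UTR site, mean high pool changes were 0.08, −0.05 and −0.19 with 0, 1 and 2 or more coding sites. With 3' UTR sites they were 0.01, −0.11 and −0.20, both without covariates. Genes with 2 or more sites lay at −0.0865 against genes with 1 site. This difference had no covariate for 3' UTR length or base composition, so these remain open for it. Pairing of the shRNA with other transcripts and binding by RBM42 itself both predict it as well. Pairing and binding cannot be told apart here, since the shRNA sequence is not in the labels. RBM42's own coding sequence holds 1 GCCCAA, as pairing at this sequence would need, but that does not exclude binding. The next lowest hexamers in the high pool, CGCCCA (z = −12.4) and CCCAAA (−10.4), overlap GCCCAA. Whether the site in RBM42 lies in such a longer sequence was not tested. A candidate explanation is therefore that part of the falls may come from the shRNA and not from the loss of RBM42.

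The spike-in factors of the low and high pools of shSCR replicate 3 lie opposite to those of the other 2 shSCR gradients. An exchange of the 2 factors is consistent with the values: once exchanged, both lie within 0.928 SD (log2, of 2 gradients) of the others. An exchange of the libraries is argued against, as the low library correlated better with the other shSCR low than with their high libraries, by 1.03. As deposited, the factor of the low pool is 2.52 times that of replicate 2. In the high pool the factor of replicate 2 is 2.63 times that of replicate 3. Once exchanged, the low and high factors were 0.543 and 1.43, against 0.568 and 1.43 in replicate 2 and 0.755 and 2.60 in replicate 1. A different spike-in volume cannot be told apart, because the volume of each pool is not given. No biological explanation, such as a difference between the replicates, was tested. With the factors exchanged the high pool's share was 59.8 ± 10.8% in shSCR (n = 3) and the low pool's 20.5 ± 6.05%, values that the choice of the exchange draws together and that test no effect of the shRNA.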
